A study of Mus musculus with 6 samples.

How the data were processed

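RNA was measured in whole kidney tissue of 6 samples from male C57BL/6 mice, 3 from the control group and 3 from the kidney stone group. Per the labels' protocols, total RNA was extracted with TRIzol and fragmented, the second cDNA strand was made with dUTP in place of dTTP, and adaptor-ligated, amplified libraries were circularised into DNA nanoballs. The dUTP step keeps the strand of origin in the library. Whether the authors used the strand when they assigned fragments to genes is not given in the sources used here, so overlapping and antisense genes stay uncertain. Reads were aligned with HISAT2 2.0.4 to the mouse genome build GRCm38.p6, per the submitters' processing notes. The program that quantified genes, its version and the gene annotation are not given in the sources used here.

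The deposited table holds FPKM values made by the authors, which are fragments normalized for gene length and for the total of the sample, with 2 decimals. Each sample has its own column, with no pooling, and 0 columns belong to other samples. The columns sum to different totals, from 609705 to 758514, and which total the authors divided by is not given in the sources used here. FPKM carry no counts, so no count model was used. Absolute sequencing depth is unknown and no counting intervals can be given. Relative depth was estimated from 53 genes that were at 0 in at least 1 sample and in the other samples had values of at least 0.15 FPKM within 1.25 times of each other, so that these values were taken to stand for 1 fragment. Against the other samples, the value of a single fragment lay between -0.06 and 0.11 log2 units. It was positive in each control sample and negative in each stone sample. The limit of 1.25 times keeps such differences small by construction, so this measure cannot show that the libraries had like depth.

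The table lists 17933 genes by symbol. Of these symbols, 17257 matched GENCODE M21 and 17868 matched the RefSeq annotation of GRCm38.p6, from which the chromosome, start and end of named genes were taken. GENCODE marks 17051 of the genes as protein coding. 346 genes were at 0 in every sample, and 0 mitochondrially encoded genes are among the rows, so a list of these was left without values. Transcript length and GC content, needed for checks of bias, were taken from GENCODE M21 and were known for 96.2% of the genes.

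Genes with a mean of at least 1 FPKM over the 6 samples were tested, 12319 in all, and 5614 were not tested. Values were transformed to log2(FPKM + 1), and a fold change is a difference on this scale, which understates the change of genes with low FPKM. Stone and control groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend), two-sided, with the Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05 on the adjusted p. Values are given as mean ± SD with 3 samples per group. The labels give 3 samples per group and do not say in so many words that each came from a separate mouse. The p-values measure only the spread between these samples, which may be technical. A rank or permutation test of 1 gene in 3 against 3 samples cannot go below p = 0.1.

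Of 37 gene lists fixed before the data were examined, 32 had at least 5 tested members and were compared with all other tested genes by limma's camera with a preset correlation between genes of 0.01, with the Benjamini-Hochberg adjustment over the 32 lists. Camera with an estimated correlation and fry were run beside it. For each list the members that passed over all genes tested were counted, and also those that passed when p was adjusted over the list alone. The genes named in the text were chosen by a rule fixed before the data were examined. The rule takes Ezh2 and the rest of the Polycomb list, the 12 genes with the largest rise and the 12 with the largest fall among called genes with a real symbol whose groups did not overlap, and the 5 most abundant genes. It also takes the called members of each list with the smallest p, up to 3 where camera called the list and 1 otherwise, and the leading called member that went against the majority of its list. Where a list had no called member, the member with the smallest p was taken. Any other gene is said to have been chosen after its values were seen.

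The scripts were tested on simulated data before use. Normal values were drawn for the 12319 genes from the real means and spreads, 200 genes were changed, and 1 list was shifted. The comparison of stone and control groups recovered 41.1% of genes changed by 0.5 on the log2 scale, 85.5% of those changed by 1 and 100% of those changed by 2. Of 166 calls 12 were false, the shifted list was called and 0 other lists were. The shifted list was that of collagens and other matrix proteins, moved by 1. The recovery rates cover only the 200 changed genes, so they do not show how well the genes of this list were recovered. Genes were drawn independently of each other and few were changed. These rates, and the 0 other lists called, therefore need not hold for the real data, where genes move together.

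The alternatives tried were pseudocounts of 0.1 and 5, no filter on low values, a mean of at least 5 FPKM, samples rescaled to equal FPKM sums, median-of-ratios scaling, quantile normalization, eBayes without a trend and with a robust fit, array weights, a minimum log2 fold change of 1, the replicate number as a block, leaving out each sample in turn, camera with an estimated correlation, and fry. A scaling to equal length-weighted totals without the gene Kap was added after the data were seen. Permutation tests of list medians used 1e+05 resamples and were two-sided. They shuffled genes, so their p-values treat genes as independent and do not measure the spread between samples. Plots were drawn with matplotlib in Python.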

Results

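Kidney RNA was compared between 3 samples from mice given glyoxylic acid and 3 samples from control mice given saline. Glyoxylic acid is a precursor of oxalate, and 120 mg/kg was injected into the peritoneum daily for 12 days to produce calcium oxalate crystals in the kidney. The title of the series names EZH2, the transition of macrophages into myofibroblasts, and kidney fibrosis caused by the crystals. The question put to the data was which transcripts differed between stone and control kidneys, with Ezh2 and the genes of macrophages, myofibroblasts and matrix looked at in particular. Expression was available as FPKM for 17933 genes, of which 15905 to 16528 were above 0 in a given sample. FPKM sums were 758514, 756744 and 711768 in control samples 1 to 3 and 613885, 609945 and 609705 in stone samples 1 to 3. On log2(FPKM + 1) values, Pearson's r across genes lay between 0.979 and 0.991 within groups and between 0.931 and 0.950 across groups. The first principal component held 78.1% of the variance and separated stone from control samples, and the second held 9% and spread the stone samples.

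Stone kidneys differed from control kidneys over much of the transcriptome. Transcripts of tubule injury, crystal-binding proteins, matrix, macrophages, complement and cell division were higher, while those of proximal tubule transport, fatty acid oxidation, oxidative phosphorylation and hemoglobin were lower. As lists these were called by limma camera with a preset correlation between genes, with an estimated correlation none of them was (adjusted p of 0.226 or more), and the crystal-binding list was also lost with equal FPKM sums (adjusted p = 0.0924). Lcn2, which encodes the injury marker NGAL, rose from 5.91 ± 1.46 FPKM (SD, n = 3) to 652 ± 388 FPKM (SD, n = 3). Slc22a7, an organic anion transporter of the proximal tubule, fell from 181 ± 23.8 FPKM to 1.48 ± 1.02 FPKM (SD, n = 3 each). By limma with Benjamini-Hochberg adjusted p below 0.05, 5356 of 12319 tested genes were higher and 1711 lower in stone kidneys, which is 57.4% of the genes tested, and 75.8% of the calls were higher. The groups did not overlap for 8165 tested genes (66.3%, against 10% by chance for 3 against 3), and 7005 genes were both called and separate. With a log2 fold change of at least 1 as well, 902 genes were higher and 245 lower.

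The balance of higher and lower calls depended on how samples were scaled. As deposited, the median log2 fold change of all tested genes was 0.21, so the typical gene was already above 0. Median-of-ratios scaling moved that median by -0.22 and gave 2776 higher and 3222 lower genes (46.3% of calls higher), quantile normalization moved it by -0.24 and gave 2762 and 3108 (47.1%), and equal FPKM sums moved it by 0.24 and gave 8440 and 797 (91.4%). Under these alternatives, 0 genes called in the deposited scale were called in the other direction. Changes smaller than this shift have no settled direction, and for each gene list the number of calls after median-of-ratios scaling is given beside the number as deposited. Kap, the kidney androgen-regulated protein of the proximal tubule, was the most abundant transcript. Its share of the FPKM sum was 23.2%, 19.3% and 20.4% in control samples 1 to 3 and 1.18%, 2.26% and 1.43% in stone samples 1 to 3.

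**Figure D1:**
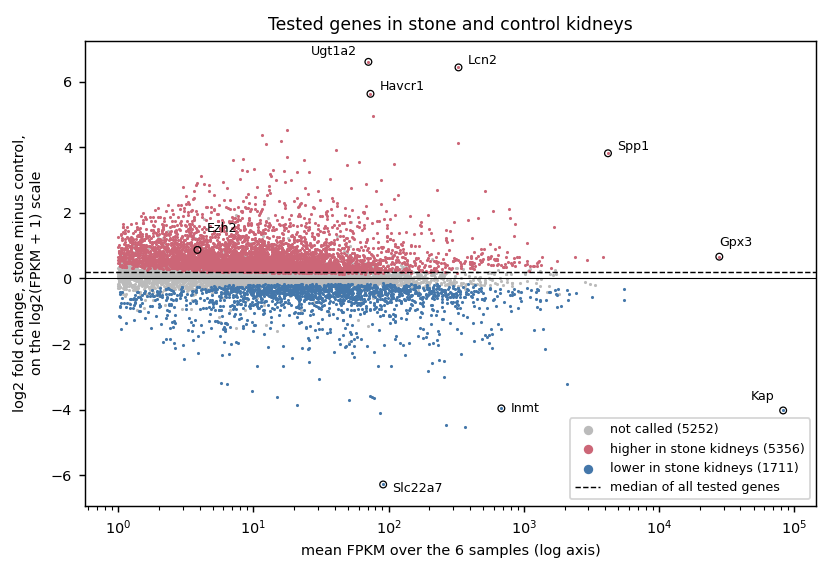
Mean FPKM over the 6 samples (log axis) against the log2 fold change of stone minus control on the log2(FPKM + 1) scale for the 12319 tested genes, with 1 point per gene, coloured by the limma call, and the dashed line at the median of all tested genes (0.21). The 5356 higher genes outnumber the 1711 lower ones in the deposited scale (2776 and 3222 after median-of-ratios scaling), and Kap lies alone at the far right among the lower genes.

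Ezh2 was higher in stone kidneys. Ezh2 encodes the catalytic histone methyltransferase subunit of Polycomb repressive complex 2 and lies on chromosome 6 from 47530274 to 47595270 on the minus strand (GRCm38.p6). It measured 2.28, 2.29 and 2.75 FPKM in control samples 1 to 3 and 5.39, 5.03 and 5.43 FPKM in stone samples 1 to 3, or Ezh2 means of 2.44 ± 0.269 against 5.28 ± 0.220 (SD, n = 3 each). The log2 fold change was 0.87 with an SE of 0.092 (limma, adjusted p = 0.000339), and all 3 stone values lay above all 3 control values. After median-of-ratios scaling the change was 0.67 (limma, adjusted p = 0.000848). Ezh2 ranked at percentile 90.1 of all tested genes by log2 fold change and at position 914 by p.

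The rest of the Polycomb list changed less than Ezh2 and mostly within the shift set by scaling. Of 12 tested members of Polycomb repressive complex 2 and the demethylases of its histone mark, 6 rose as deposited (6 adjusted over the list alone) and 0 fell, 2 rose and 1 fell after median-of-ratios scaling, and 10 rose and 0 fell with equal FPKM sums. Rbbp7, a histone-binding subunit, rose from 59.0 ± 2.86 to 81.0 ± 2.05 FPKM (limma, adjusted p = 0.000817, and 0.0403 after median-of-ratios scaling). The core subunit gene Eed, the accessory subunit gene Aebp2 and the demethylase genes Kdm6a and Kdm6b rose as deposited, with log2 fold changes of 0.28, 0.30, 0.47 and 0.33. After median-of-ratios scaling these 4 calls were lost, with log2 fold changes of 0.05, 0.06, 0.26 and 0.10. Quantile normalization lost them as well. The Aebp2 and Kdm6b calls were also lost with totals without Kap and without control sample 1 or 2 or stone sample 2 or 3. The Kdm6b call was lost with no filter and the Eed call without stone sample 3. Ezh1, the paralog of Ezh2, was at 17.6 ± 1.26 and 19.7 ± 0.835 FPKM (SD, n = 3 each) and did not pass (limma, adjusted p = 0.0999). Suz12, Mtf2, Phf1 and Jarid2 did not pass either, with log2 fold changes of 0.09, 0.10, 0.14 and -0.22. With equal FPKM sums Ezh1, Suz12, Mtf2 and Phf1 were called higher, at 0.42, 0.35, 0.34 and 0.41 (limma, adjusted p = 0.00331, 0.0169, 0.0065 and 0.00804), and Ezh1 was also called higher with array weights, at 0.15 (limma, adjusted p = 0.0303). Mtf2 was called lower after quantile normalization, at -0.23 (limma, adjusted p = 0.0307). Jarid2 was called lower with array weights, at -0.48, and without control sample 3, at -0.43 (limma, adjusted p = 0.0192 and 0.026). Rbbp4 stood at -0.15 as deposited (limma, adjusted p = 0.105) and fell by 0.40 after median-of-ratios scaling (limma, adjusted p = 0.00423), by 0.29 after quantile normalization (limma, adjusted p = 0.00943) and by 0.20 with totals without Kap (limma, adjusted p = 0.0431). Phf19 was too low to be tested, at 0.427 and 0.683 FPKM on average in control and stone kidneys. The list as a whole was not called (limma camera, adjusted p = 0.449, and 0.747 with an estimated correlation), though fry passed it (adjusted p = 0.00404).

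Genes of myofibroblasts and of the matrix rose together. Of 13 tested myofibroblast and mesenchymal markers, 10 rose (13 adjusted over the list alone) and 0 fell, with 9 higher after median-of-ratios scaling. Vim, an intermediate filament gene of mesenchymal cells, rose from 18.7 ± 2.54 to 60.8 ± 12.4 FPKM, and Tagln, a smooth muscle actin-binding protein gene, from 12.9 ± 1.65 to 44.7 ± 10.3 FPKM (SD, n = 3 each). Itgb1, the integrin beta 1 gene, rose by 0.80 on the log2 scale. Acta2, which encodes the smooth muscle actin used to define myofibroblasts and was picked out after its values were seen, rose from 10.1 ± 1.00 to 34.7 ± 10.2 FPKM (limma, adjusted p = 0.000688). Postn, Myl9 and Cnn1, also picked out after their values were seen, did not pass over all genes tested (limma, adjusted p = 0.0554, 0.0639 and 0.0658). Whole kidney RNA does not show which cells made the transcripts of this list. Camera called the list upward (limma, adjusted p = 0.00779), but not with samples rescaled to equal FPKM sums (adjusted p = 0.0924) and not with an estimated correlation (adjusted p = 0.494). Equal FPKM sums shifted the typical gene upward as well, and the median of this list went from 0.983 to 1.205, with 13 members called higher.

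Matrix proteins showed the same direction in nearly every tested gene. Among collagens and other matrix proteins, 24 of 25 tested members rose (25 adjusted over the list alone) and 24 rose after median-of-ratios scaling, with a median log2 fold change of 1.63 (limma camera, adjusted p = 2.24e-06, and 0.41 with an estimated correlation). The basement membrane collagen genes Col4a1 and Col4a2 rose from 31.2 ± 2.48 to 99.4 ± 7.37 FPKM and from 21.1 ± 2.75 to 70.0 ± 7.31 FPKM, and Col18a1 rose by 1.39 on the log2 scale. The fibrillar collagen gene Col1a1, picked out after its values were seen, rose from 2.71 ± 0.569 to 23.6 ± 7.52 FPKM (SD, n = 3 each). Of 18 tested matrix remodelling enzymes and inhibitors, 16 rose and 1 fell (16 and 1 adjusted over the list alone), with 14 and 1 after median-of-ratios scaling (limma camera, adjusted p = 0.00165, and 0.406 with an estimated correlation). Timp1, a metalloproteinase inhibitor gene, rose from 0.517 ± 0.504 to 34.8 ± 14.3 FPKM, the matrilysin gene Mmp7 from 0.167 ± 0.215 to 7.35 ± 1.18 FPKM, and the transglutaminase gene Tgm2 by 0.84 on the log2 scale. Timp3, another inhibitor gene, fell by 0.29, a call that was lost with equal FPKM sums (limma, adjusted p = 0.945). The Timp3 call was also lost with no filter, after quantile normalization, and without control sample 1 or 3 or stone sample 2 or 3.

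In the list of the TGF-beta pathway and mesenchymal transcription factors, 13 of 17 tested members rose (13 adjusted over the list alone) and 0 fell, with 12 higher after median-of-ratios scaling. Tgfb1, the ligand gene, rose from 6.86 ± 1.18 to 24.2 ± 4.78 FPKM and Tgfbr1, a receptor gene, from 11.3 ± 0.660 to 21.6 ± 1.12 FPKM (SD, n = 3 each). Ltbp2, a latent TGF-beta binding protein family member, rose by 1.49 on the log2 scale. Camera called the list upward (limma, adjusted p = 0.00748), but not with equal FPKM sums (adjusted p = 0.0742) or with an estimated correlation (adjusted p = 0.494). With equal FPKM sums, which shifted the typical gene upward as well, the median went from 0.803 to 1.023, with 15 members higher and 0 lower.

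Macrophage transcripts were more abundant in stone kidneys. Of 22 tested macrophage and monocyte markers, 20 rose and 1 fell (20 and 1 adjusted over the list alone and after median-of-ratios scaling alike), with a median log2 fold change of 1.67 (limma camera, adjusted p = 0.000305, and 0.503 with an estimated correlation). The complement genes C1qa and C1qc, which tissue macrophages express, rose from 13.7 ± 0.696 to 69.1 ± 20.3 FPKM and from 9.50 ± 0.495 to 46.5 ± 13.3 FPKM (SD, n = 3 each). Ccr2, a chemokine receptor gene of recruited monocytes, rose from 0.80 ± 0.157 to 4.92 ± 1.14 FPKM. Ly6c2, another gene of inflammatory monocytes, fell from 1.62 ± 0.263 to 0.577 ± 0.259 FPKM (limma, adjusted p = 0.00647). Its reads can be shared with the close paralog Ly6c1, so this value is uncertain.

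Genes of alternative activation and lipid-associated macrophages rose in 10 of 12 tested members and fell in 1 (10 and 1 adjusted over the list alone, 9 and 1 after median-of-ratios scaling). Apoe, a lipid carrier gene, rose from 137 ± 21.4 to 887 ± 173 FPKM and Lgals3, the galectin-3 gene, from 23.4 ± 4.10 to 112.5 ± 17.1 FPKM (SD, n = 3 each). Chil3, a chitinase-like protein gene, rose from 0.0967 ± 0.119 to 3.84 ± 0.318 FPKM. Folr2, a folate receptor gene of resident macrophages, fell by 0.38 on the log2 scale (limma, adjusted p = 0.0331), and that call was lost with equal FPKM sums (adjusted p = 0.158). The Folr2 call was also lost with the replicate block and without control sample 1 or 2 or stone sample 2 or 3. The list was called upward (limma camera, adjusted p = 0.032), but not with equal FPKM sums (adjusted p = 0.215), without control sample 3 (adjusted p = 0.0791) or with an estimated correlation (adjusted p = 0.494). Its median was 1.479 as deposited and 1.58 with equal FPKM sums, which shifted the typical gene upward as well. Apoe, Lgals3 and several others are also expressed by kidney epithelium. Of the genes of classical activation, 6 were tested, 2 rose and 1 fell (2 and 1 adjusted over the list alone and after median-of-ratios scaling, 3 and 1 with equal FPKM sums), and the list was not called (limma camera, adjusted p = 0.724). The interferon-induced chemokine gene Cxcl10 rose by 1.20 on the log2 scale, and the transcription factor gene Irf5 fell by 0.93.

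Chemokines and complement moved with the macrophage markers. Among chemokines and growth factors for myeloid cells, 11 of 16 tested members rose (11 adjusted over the list alone) and 0 fell, with 10 higher after median-of-ratios scaling (limma camera, adjusted p = 0.00202, and 0.365 with an estimated correlation). The macrophage growth factor gene Csf1 rose from 2.34 ± 0.506 to 31.4 ± 1.44 FPKM, the monocyte chemoattractant gene Ccl2 from 0.677 ± 0.136 to 15.9 ± 3.13 FPKM, and Cxcl16 from 22.5 ± 1.42 to 58.9 ± 0.949 FPKM (SD, n = 3 each). Of 12 complement components tested, 11 rose (11 adjusted over the list alone) and 0 fell, with 10 higher after median-of-ratios scaling (limma camera, adjusted p = 0.00196, and 0.226 with an estimated correlation). C3, the central component, rose from 4.46 ± 3.35 to 149 ± 26.2 FPKM. Cfi and C4b rose by 2.48 and 1.86 on the log2 scale.

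All 8 tested genes of MHC class II presentation rose (8 adjusted over the list alone and after median-of-ratios scaling), with a median log2 fold change of 0.98 (limma camera, adjusted p = 0.00444, and 0.365 with an estimated correlation). Cd74, the invariant chain gene, rose from 180 ± 9.47 to 405.5 ± 56.7 FPKM (SD, n = 3 each), and the peptide-exchange genes H2-DMb1 and H2-DMa by 1.57 and 1.45 on the log2 scale. Of the neutrophil markers 3 were tested and all 3 rose, among them S100a9 from 1.15 ± 0.508 to 8.59 ± 1.06 FPKM, but S100a9 is also expressed by other myeloid cells, and the list was too short for a set test. Of the markers of T and NK cells 0 reached the level for testing. Mzb1, the tested marker of B and plasma cells, had 1.49 ± 0.446 and 1.15 ± 0.535 FPKM and did not pass (limma, adjusted p = 0.412), but was called lower after quantile normalization (limma, adjusted p = 0.029). Among 17 tested interferon-stimulated genes, 2 rose (1 adjusted over the list alone and 1 after median-of-ratios scaling, but 8 with equal FPKM sums, and 1 rose and 2 fell after quantile normalization), led by Ifit2 at a log2 fold change of 1.18, and the list was not called (limma camera, adjusted p = 0.692). Its camera direction was downward while its median was 0.18, since camera compares a list with other genes, most of which were above 0.

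**Figure D2:**
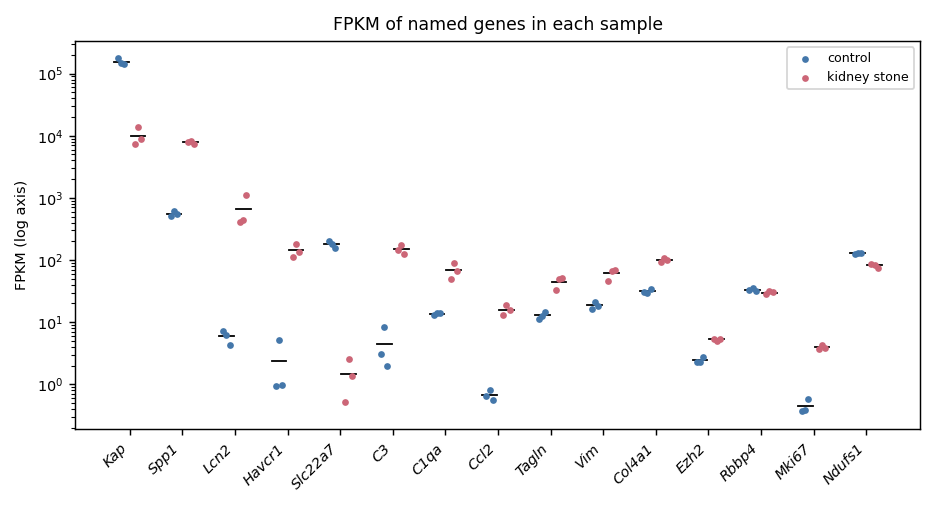
FPKM (log axis) of 15 named genes in each sample, with 1 point per sample, 3 control and 3 kidney stone samples per gene, and a bar at each group mean. The 3 stone samples lie above the 3 control samples for Ezh2, Spp1, Lcn2, Havcr1, C3, C1qa, Ccl2, Tagln, Vim, Col4a1 and Mki67 and below them for Kap, Slc22a7, Rbbp4 and Ndufs1, and Rbbp4 did not pass the test (limma, adjusted p = 0.105).

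Tubule injury genes had the largest median rise of the 32 lists. Of 22 tested members 21 rose (21 adjusted over the list alone and after median-of-ratios scaling) and 0 fell, with a median log2 fold change of 2.51 (limma camera, adjusted p = 5.23e-08, and 0.226 with an estimated correlation). Havcr1, which encodes the proximal tubule injury marker KIM-1 and lies on chromosome 11 from 46739822 to 46779578 (GRCm38.p6), rose from 2.39 ± 2.45 to 145 ± 36.1 FPKM (SD, n = 3 each). The repair transcription factor gene Sox9 rose from 0.123 ± 0.0231 to 7.49 ± 0.691 FPKM, the cell cycle inhibitor gene Cdkn1a from 3.45 ± 0.459 to 34.7 ± 5.14 FPKM, and the TWEAK receptor gene Tnfrsf12a from 21.2 ± 3.61 to 139 ± 4.70 FPKM. Fgg, the fibrinogen gamma chain gene, rose from 4.26 ± 1.05 to 77.6 ± 14.5 FPKM. Lcn2 had a log2 fold change of 6.43 with an SE of 0.369 (limma, adjusted p = 3.36e-05), and its stone value was 1099 FPKM in stone sample 3 against 410.1 and 446.5 in stone samples 1 and 2.

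Genes for proteins that bind crystals or form the stone matrix rose in 12 of 16 tested members and fell in 1 (12 and 1 adjusted over the list alone, 11 and 2 after median-of-ratios scaling). Spp1, the osteopontin gene on chromosome 5 from 104435111 to 104441053 (GRCm38.p6), rose from 556 ± 54.3 to 7828 ± 473 FPKM (SD, n = 3 each), a log2 fold change of 3.82 with an SE of 0.101 (limma, adjusted p = 5.81e-06), and was among the 5 most abundant transcripts. The matrix Gla protein gene Mgp rose from 60.4 ± 9.39 to 397 ± 77.7 FPKM and the annexin gene Anxa5 from 65.7 ± 0.354 to 149 ± 7.90 FPKM. Itih2, which encodes a heavy chain of inter-alpha-trypsin inhibitor, fell from 4.70 ± 0.299 to 0.50 ± 0.330 FPKM. Camera called the list upward (limma, adjusted p = 0.0146), but not with equal FPKM sums (adjusted p = 0.0924) or with an estimated correlation (adjusted p = 0.36). With equal FPKM sums, which shifted the typical gene upward as well, the median went from 1.756 to 2.017, with 13 members higher and 1 lower. Of 16 tested genes of glyoxylate and oxalate metabolism and transport, 7 fell and 3 rose (7 and 3 adjusted over the list alone, 10 and 1 after median-of-ratios scaling), but 3 fell and 6 rose with equal FPKM sums. The aminotransferase gene Agxt2 fell by 1.09 on the log2 scale and the glyoxylate reductase gene Grhpr fell from 224 ± 24.0 to 134 ± 3.96 FPKM, whereas Prodh2, a hydroxyproline dehydrogenase gene of a pathway that ends in glyoxylate, rose from 45.3 ± 7.37 to 107 ± 15.1 FPKM. The list was called downward (limma camera, adjusted p = 0.00165), but not after quantile normalization (adjusted p = 0.244) or with an estimated correlation (adjusted p = 0.387), and its median of -0.22 became 0.03 with equal FPKM sums.

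Proximal tubule transcripts fell in most, but not all, tested markers. Of 22 tested markers 15 fell and 2 rose (15 and 3 adjusted over the list alone, 17 and 2 after median-of-ratios scaling, 13 and 4 with equal FPKM sums), with a median log2 fold change of -0.70 (limma camera, adjusted p = 8.63e-09, and 0.267 with an estimated correlation). Kap, on chromosome 6 from 133849855 to 133853667 (GRCm38.p6), fell by 4.02 on the log2 scale with an SE of 0.262 (limma, adjusted p = 5.42e-05). The amino acid transporter gene Slc7a13 fell from 704 ± 46.5 to 31.1 ± 13.4 FPKM, the phosphate and urate transporter gene Slc17a3 from 222 ± 10.9 to 43.8 ± 5.39 FPKM, and the organic anion transporter family gene Slc22a30 from 182 ± 16.5 to 28.1 ± 3.99 FPKM (SD, n = 3 each). The sulfate transporter gene Slc13a1 rose from 170 ± 6.76 to 373 ± 58.8 FPKM. Slc7a13, Kap and Slc22a30 are known for higher expression in male than in female mouse kidney.

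Solute carriers and other transporters of organic ions and drugs fell in 10 of 15 tested members and rose in 2 (10 and 2 adjusted over the list alone and after median-of-ratios scaling, 8 and 4 with equal FPKM sums), with a median log2 fold change of -0.61 (limma camera, adjusted p = 2.36e-05, and 0.265 with an estimated correlation). Slc22a7 fell by 6.28 on the log2 scale with an SE of 0.280 (limma, adjusted p = 1.47e-05), the largest fall among genes with separate groups. Slc22a28 fell from 144 ± 2.61 to 21.9 ± 2.14 FPKM and the organic cation transporter gene Slc22a2 from 256 ± 22.1 to 74.7 ± 5.09 FPKM (SD, n = 3 each), while the efflux pump gene Abcc4 rose from 8.89 ± 1.16 to 24.4 ± 2.22 FPKM. Slc22a19, Slc22a28 and Slc22a30 are close paralogs, and how fragments were split among them is not known.

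Of 20 tested genes of steroid and xenobiotic metabolism, 12 fell and 6 rose (12 and 6 adjusted over the list alone, 12 and 4 after median-of-ratios scaling, 9 and 8 with equal FPKM sums). Ugt3a1, a glycosyltransferase gene, fell from 195 ± 4.45 to 48.9 ± 7.16 FPKM and Cyp51, a cholesterol synthesis gene, from 90.9 ± 7.42 to 25.9 ± 2.55 FPKM (SD, n = 3 each). Ugt1a2 had the largest rise of any gene with separate groups, from 0.497 ± 0.433 to 141 ± 22.1 FPKM. Genes of the Ugt1a locus share their last exons, so reads from another Ugt1a transcript could be counted for it. The list was called downward (limma camera, adjusted p = 0.000305), but not after quantile normalization (adjusted p = 0.123) or with an estimated correlation (adjusted p = 0.226).

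The remaining genes with the largest changes were of several kinds. Upward, the protease inhibitor gene Serpina3n rose by 4.38 on the log2 scale, the cytokine signalling inhibitor gene Socs3 by 4.17, the glutathione transferase gene Gsta1 by 4.08 and the scaffold protein gene Akap12 by 3.71. Serpina3n and Gsta1 belong to families of similar copies, and their values are uncertain for that reason. Downward, the methyltransferase gene Inmt fell from 1283 ± 102 to 82.1 ± 14.1 FPKM and the steroid hydroxylase gene Cyp7b1 from 162 ± 12.7 to 10.6 ± 7.70 FPKM (SD, n = 3 each). Pzp, Slc22a19, Akr1c14, Akr1c18, Mep1b and Slco1a1 fell by 3.85, 3.71, 3.64, 3.62, 3.60 and 3.59 on the log2 scale. Among these are genes for a plasma protease inhibitor, aldo-keto reductases of steroids, a brush border protease and an organic anion transporter, and the aldo-keto reductase pair has closely similar sequences. Besides Kap and Spp1, the 5 most abundant genes were Gpx3, Fxyd2 and Fth1. The plasma glutathione peroxidase gene Gpx3 rose by 0.66, a call lost after median-of-ratios scaling and with no filter (limma, adjusted p = 0.161 and 0.446). The Gpx3 call was also lost without control sample 1 or stone sample 1. Fxyd2, a regulator gene of the sodium pump, fell from 6775 ± 555 to 4281 ± 272 FPKM, and the ferritin gene Fth1 fell by 0.32, a call lost with equal FPKM sums (limma, adjusted p = 0.693). The Fth1 call was also lost with no filter, after quantile normalization, with the replicate block, and without control sample 1 or any stone sample.

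Oxidative phosphorylation and fatty acid oxidation genes mostly fell, and glycolysis genes did not move as a list. Of 23 tested subunits of oxidative phosphorylation encoded in the nucleus, 16 fell and 0 rose as deposited. The number that fell was 16 adjusted over the list alone and 20 after median-of-ratios scaling. With equal FPKM sums 9 fell and 1 rose. The median log2 fold change as deposited was -0.41 (limma camera, adjusted p = 3.17e-10, and 0.365 with an estimated correlation). Ndufs1, Sdha and Uqcrc2, genes of complexes I, II and III, fell by 0.64, 0.53 and 0.48 on the log2 scale. Of 28 tested fatty acid oxidation genes, 17 fell and 4 rose (17 and 4 adjusted over the list alone, 18 and 2 after median-of-ratios scaling, 13 and 7 with equal FPKM sums), with a median of -0.42 (limma camera, adjusted p = 3.4e-08, and 0.365 with an estimated correlation). Acsm3, an acyl-CoA synthetase gene, fell from 505 ± 70.5 to 22.7 ± 7.16 FPKM, the fatty acid hydroxylase gene Cyp4b1 from 2353 ± 61.6 to 533 ± 60.4 FPKM, and the dehydrogenase gene Acads by 0.93 on the log2 scale (SD, n = 3 each). Against this direction, Cyp4a14, a hydroxylase gene induced through PPAR alpha, rose from 46.9 ± 48.0 to 601 ± 47.4 FPKM. In the antioxidant and ferroptosis list 9 of 22 tested members fell and 6 rose (9 and 6 adjusted over the list alone, 14 and 3 after median-of-ratios scaling), but 5 fell and 10 rose with equal FPKM sums. The superoxide dismutase genes Sod1 and Sod2 fell by 0.87 and 0.66, and Acsl4, an acyl-CoA synthetase gene that promotes ferroptosis, rose by 1.28. The list was called downward (limma camera, adjusted p = 0.00629), but not after quantile normalization (adjusted p = 0.878) or with an estimated correlation (adjusted p = 0.406), and its median of -0.20 became 0.08 with equal FPKM sums. Fry did not pass the antioxidant and ferroptosis list (adjusted p = 0.308). Of 17 tested glycolysis genes 5 rose and 3 fell (4 and 2 adjusted over the list alone, 3 and 5 after median-of-ratios scaling, 9 and 0 with equal FPKM sums), among them Pklr at 0.62 and Pgk1 at -0.37, and the list was not called (limma camera, adjusted p = 0.431, downward against a median of 0.14). The Pgk1 call was lost with equal FPKM sums (limma, adjusted p = 0.293).

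Markers of other tubule segments were looked at as well. Of 15 tested markers of the loop of Henle and distal tubule, 8 fell and 1 rose (8 and 1 adjusted over the list alone, 9 and 1 after median-of-ratios scaling), with a median of -0.40 as deposited (limma camera, adjusted p = 0.000131, and 0.226 with an estimated correlation). With equal FPKM sums 3 of them fell and 3 rose, with a median of -0.12. Egf, the epidermal growth factor gene, fell from 398 ± 50.7 to 69.9 ± 8.40 FPKM and the parvalbumin gene Pvalb of the early distal tubule from 18.7 ± 2.05 to 0.840 ± 0.123 FPKM, while the calcium channel gene Trpv5 rose from 6.01 ± 0.248 to 14.8 ± 3.17 FPKM (SD, n = 3 each). Of 17 tested collecting duct markers 5 rose and 2 fell (5 and 2 adjusted over the list alone), but 1 rose and 5 fell after median-of-ratios scaling, and the list was not called (limma camera, adjusted p = 0.277, downward against a median of 0.16). Slc4a1, the anion exchanger gene of intercalated cells and red blood cells, fell by 0.82. Among 20 tested genes of calcium and phosphate handling, 9 rose and 7 fell (9 and 8 adjusted over the list alone, 7 and 8 after median-of-ratios scaling, 9 and 4 with equal FPKM sums), the median was -0.12 and the mean 0.26, and the list was not called (limma camera, adjusted p = 0.277, and 0.507 with an estimated correlation). At a mean of at least 5 FPKM camera called this calcium and phosphate list downward (limma, adjusted p = 0.0404), whereas fry passed it upward (adjusted p = 0.00165). Stc2, the stanniocalcin-2 gene, rose from 0.873 ± 0.00577 to 6.72 ± 0.159 FPKM and the klotho gene Kl fell from 190 ± 13.1 to 119 ± 16.2 FPKM.

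Podocyte markers rose in 10 of 11 tested members (10 adjusted over the list alone, 7 after median-of-ratios scaling, 3 after quantile normalization) and 0 fell. Nes, Synpo and Podxl, which encode nestin and proteins of podocyte foot processes and surface, rose by 1.74, 1.20 and 0.73 on the log2 scale. Camera called this list upward (limma, adjusted p = 0.0309), but not at a mean of at least 5 FPKM (adjusted p = 0.0774), with equal FPKM sums (adjusted p = 0.105), without stone sample 1 (adjusted p = 0.0872) or with an estimated correlation (adjusted p = 0.494). The podocyte median was 0.515 as deposited and 0.766 with equal FPKM sums, which shifted the typical gene upward as well. Of 14 tested endothelial markers 8 rose (8 adjusted over the list alone, 7 after median-of-ratios scaling) and 0 fell, led by the endoglin gene Eng, which rose from 24.8 ± 5.44 to 53.6 ± 7.16 FPKM (SD, n = 3 each). The endothelial list was not called as deposited (limma camera, adjusted p = 0.114) and was called after median-of-ratios scaling (adjusted p = 0.0173), quantile normalization (0.0381), with array weights (0.039), with the replicate block (0.0196), without control sample 3 (0.0115) and by fry (0.0402). With an estimated correlation as deposited the endothelial adjusted p was 0.694 (limma camera).

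Cell cycle genes rose in 23 of 24 tested members (23 adjusted over the list alone, 22 after median-of-ratios scaling) and 0 fell, with a median of 1.45 (limma camera, adjusted p = 1.19e-06, and 0.365 with an estimated correlation). The proliferation marker gene Mki67 rose from 0.447 ± 0.116 to 3.92 ± 0.283 FPKM, the cyclin gene Ccnb2 from 0.917 ± 0.480 to 11.8 ± 2.53 FPKM and the mitosis gene Birc5 from 1.34 ± 0.293 to 8.89 ± 1.83 FPKM (SD, n = 3 each). Of 19 tested cell death genes, 14 rose and 1 fell (14 and 1 adjusted over the list alone, 7 and 2 after median-of-ratios scaling). The TNF receptor gene Tnfrsf1a rose by 1.22 and the mitochondrial gene Aifm1 fell by 0.45. The cell death list was not called as deposited (limma camera, adjusted p = 0.0603) and was called after median-of-ratios scaling (adjusted p = 0.0299), with no filter (0.023), totals without Kap (0.0496), array weights (0.0401), without stone sample 1 (0.0452) and by fry (0.000855). With an estimated correlation as deposited the cell death adjusted p was 0.396 (limma camera).

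Markers of blood and of neighbouring tissue were also measured. Of 6 tested red blood cell genes 5 fell and 1 rose (5 and 1 adjusted over the list alone, 5 and 0 after median-of-ratios scaling), with a median of -1.79 (limma camera, adjusted p = 6.27e-05, and 0.365 with an estimated correlation). The hemoglobin genes Hbb-bs, Hbb-bt and Hba-a2 fell from 881 ± 190 to 224.5 ± 21.9 FPKM, from 93.6 ± 19.0 to 16.8 ± 0.342 FPKM and from 677 ± 142 to 178 ± 19.0 FPKM (SD, n = 3 each), and their near-identical copies can share reads. Slc25a37, a mitochondrial iron importer gene, rose by 0.20, a call that was lost after median-of-ratios scaling with a value of -0.04. The Slc25a37 call was also lost after quantile normalization, with totals without Kap and with the replicate block. Leaving out any sample but stone sample 1 lost it too. Of 8 tested adipose markers 0 rose and 1 fell (0 and 1 adjusted over the list alone and after median-of-ratios scaling). That gene, the lipoprotein lipase gene Lpl, fell from 439 ± 102 to 75.2 ± 8.52 FPKM, and it is also expressed in the kidney. The list, with Lpl as its sole called member, had a camera adjusted p of 0.045 in limma, with a median of -0.01, an adjusted p of 0.513 after median-of-ratios scaling and 0.538 with an estimated correlation. Fry did not pass the adipose list (adjusted p = 0.544). Leaving out 1 sample moved the median of these adipose markers from -1.55 (without stone sample 3) to 1.05 (without control sample 2), and the call was lost without control sample 2, stone sample 1 or stone sample 2 (limma camera, adjusted p = 0.374, 0.0961 and 0.126). The fat cell gene Adipoq, picked out after its values were seen, was at 16.9 FPKM in control sample 2 and 22.3 FPKM in stone sample 3 and at 0.07 FPKM or less in the other 4 samples. Of 2 tested adrenal markers 1 rose, Akr1b7 by 0.52, a call lost after median-of-ratios scaling (limma, adjusted p = 0.0702). The Akr1b7 call was also lost after quantile normalization and without control sample 2 or 3 or stone sample 3.

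Several immediate early genes varied widely within the control group. Of 12 tested members 2 rose (1 adjusted over the list alone and after median-of-ratios scaling), led by the transcription factor gene Egr2, which rose from 0.810 ± 0.822 to 6.28 ± 1.62 FPKM (SD, n = 3 each). Fos, picked out after its values were seen, measured 0.92, 33.4 and 68.9 FPKM in control samples 1 to 3 and 15.1, 17.1 and 25.8 FPKM in stone samples 1 to 3. The list was not called (limma camera, adjusted p = 0.593, downward against a median of 0.52), and without control sample 1 it was called downward with a median of -0.57 (adjusted p = 0.00472).

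**Figure D3:**
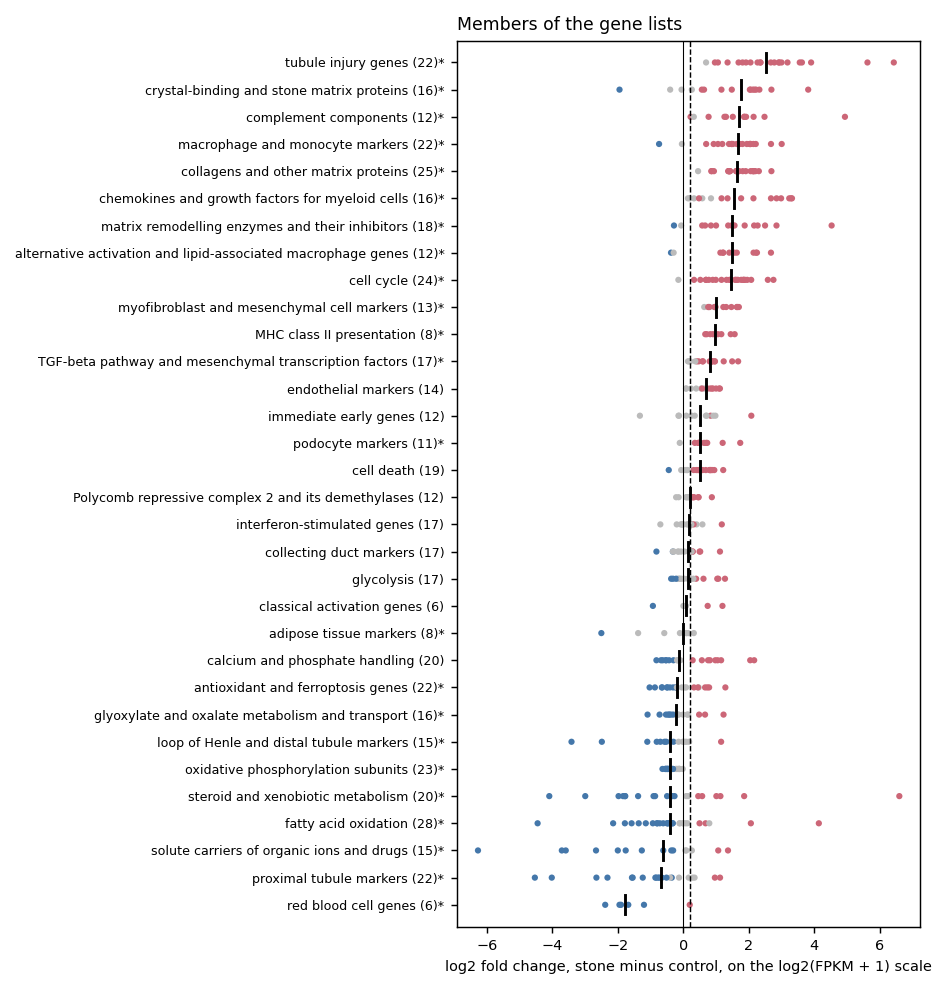
Log2 fold change of stone minus control on the log2(FPKM + 1) scale (horizontal axis) for the tested members of 32 gene lists, with 1 point per gene, red where limma called it higher, blue where lower and grey where not called, a black bar at each list's median, the number of tested members in parentheses, an asterisk where limma's camera with the preset correlation called the list, and a dashed line at the median of all tested genes (0.21). Medians run from -1.79 for red blood cell genes to 2.51 for tubule injury genes, and 23 lists carry an asterisk, of which 0 do so with an estimated correlation.

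By camera with the preset correlation, 23 of the 32 lists moved, 13 upward and 10 downward. With a correlation estimated from these 6 samples 0 lists were called by limma camera, the smallest adjusted p was 0.226, and 5 lists had an unadjusted p below 0.05. By fry, which asks whether the genes of a list moved on balance in 1 direction and makes no comparison with other genes, 25 lists passed (limma, Benjamini-Hochberg adjusted).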

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

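The scaling to equal totals without Kap was chosen after the data were seen, and the other alternatives were fixed before. Ezh2 is left out by a mean of at least 5 FPKM and was not tested there. It stayed higher and called under the other alternatives except a minimum log2 fold change of 1. Its 0.871 on the log2(FPKM + 1) scale misses that minimum. The ratio of its mean FPKM, stone over control, was 2.165, and the added 1 lowers the log2 fold change at such low values. Leaving out 1 sample gave Ezh2 values of 0.838 to 0.935 (limma, adjusted p from 0.000748 to 0.00247), 4265 to 5242 higher genes, 1360 to 1697 lower genes and 22 to 24 lists. Of 113 other named genes that were called, 102 kept their call and direction under each alternative in which they were tested, the minimum log2 fold change aside, and 11 did not. A mean of at least 5 FPKM leaves out 15 of the 113.

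Scaling changed the balance of higher and lower genes. Equal FPKM sums gave 8440 higher and 797 lower genes, median-of-ratios scaling 2776 and 3222, quantile normalization 2762 and 3108, and totals without Kap 4631 and 1967. A log2 fold change of at least 1 as well left 902 and 245 by construction. Pseudocounts of 0.1 and 5 gave 5356 and 5337 higher and 1709 and 1710 lower genes. No filter gave 5853 and 1761 of 17587 tested, and a mean of at least 5 FPKM gave 3859 and 1536 of 9019. Array weights gave 6534 and 2213. With the replicate block there were 4861 higher and 1517 lower genes. The deviations of samples with the same number from their group means correlated at 0.007, -0.22 and -0.04, so the numbers were not taken to pair samples.

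Some genes turned in sign, and some lists that were not called turned in camera's direction. That direction is relative to other genes and rests on fold changes divided by their standard errors, so it can differ from that of a median. With equal FPKM sums Rbbp4 was at 0.125 and Jarid2 at 0.037. With median-of-ratios scaling Ezh1 was at -0.086, Suz12 at -0.151, Mtf2 at -0.118, Phf1 at -0.095 and Slc25a37 at -0.044, and camera's direction turned for the classical activation list, whose median of -0.146 also turned, and for the immediate early list, whose median of 0.271 did not. With quantile normalization Ezh1 was at -0.040, Eed at -0.009, Suz12 at -0.166, Mtf2 at -0.227, Phf1 at -0.097 and Slc25a37 at -0.044, and camera's direction turned for the Polycomb list, whose median of -0.024 also turned, and for the calcium and phosphate, glycolysis and immediate early lists, whose medians of -0.243, 0.102 and 0.421 kept their sign. With array weights camera's direction turned for the immediate early list, at a median of 2.001. Other list medians turned without a turn in camera's direction. After median-of-ratios scaling these were Polycomb (-0.018), interferon-stimulated genes (-0.014), collecting duct (-0.078) and glycolysis (-0.113). After quantile normalization they were classical activation (-0.235), interferon-stimulated genes (-0.151) and collecting duct (-0.109). With equal FPKM sums they were calcium and phosphate (0.139), glyoxylate and oxalate (0.032), antioxidant (0.078) and adipose (0.091). Equal FPKM sums and median-of-ratios scaling moved the typical gene by 0.242 and -0.224. Each gene and list median that turned under these scalings had been closer to 0 than that shift. Such turns follow from the scaling itself, and the cause of the other turns was not tested. Leaving out 1 sample gave medians of -0.565 (without control sample 1) to 1.284 (without control sample 3) for immediate early genes and 0.087 to 0.305 for interferon-stimulated genes. The range was -0.131 to 0.049 for calcium and phosphate handling, 0.005 to 0.251 for collecting duct markers and 0.029 to 0.242 for classical activation genes.

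Camera with an estimated correlation called 0 lists, against 23 with the preset correlation and 25 by fry, and 5 lists had an unadjusted p below 0.05. The estimate from 6 samples is the sole difference between the camera settings. Fry makes no comparison with other genes, and its direction differed from camera's for the lists of classical activation (median 0.073), interferon-stimulated genes (0.177), collecting duct (0.156), calcium and phosphate handling (-0.119), glycolysis (0.143) and immediate early genes (0.519). Absolute depth is unknown, so how far low genes are limited by counting could not be computed.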

Other observations

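Of the tests in this part, those on the loss of Kap, on the splits of the samples and on a lower share of proximal tubule cells were chosen only after the result was seen, as were the 5 gene lists named here and the genes named here that lie outside the fixed rule, such as Cyp4a12b, Cfd, Ucp1 and Egr1.

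Lists of genes of the acute phase, of IL-6 family signalling and of retinoid metabolism were drawn up because such genes had been seen among the large rises, so their counts describe the genes and test nothing. Of 10 tested genes for acute-phase and plasma proteins 8 rose and 0 fell, with a median log2 fold change of 2.64. The ceruloplasmin gene Cp rose from 8.51 to 112 FPKM on average and the endotoxin-binding protein gene Lbp from 1.13 to 7.25 FPKM. Of 12 tested IL-6 family and STAT3 feedback genes 10 rose and 1 fell, with a median of 1.32. The transcription factor gene Stat3 rose from 16.3 to 51.5 FPKM, the oncostatin M receptor gene Osmr by 2.39 on the log2 scale and the cytokine gene Lif from 0.0967 to 3.04 FPKM, while the receptor gene Lifr fell by 0.47 on the log2 scale. Of 8 tested retinoid metabolism genes 5 rose and 0 fell, with a median of 1.47. The retinaldehyde dehydrogenase gene Aldh1a1 rose from 2.71 to 44.9 FPKM and Aldh1a2 by 3.04 on the log2 scale. After median-of-ratios scaling 8, 9 and 4 genes of these lists were higher.

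More genes were higher than lower as deposited, and Kap took 7.27% to 8.78% of the length-weighted FPKM sum, which stands closer to reads than the plain sum, in control samples against 0.38% to 0.72% in stone samples. A loss of Kap reads from the total could raise all other genes. With Kap left out of the length-weighted total, the median of all tested genes was 0.168 (0.145 to 0.191 when 1 sample was left out), against 0.212 as deposited. For such a total this argues against the loss of Kap as the whole cause. The authors' gene lengths and the total they divided by are not given. The rescaling also evened out length-weighted totals that differed between groups, so how much Kap contributed is not settled. Median-of-ratios scaling and quantile normalization set the median near 0 by construction, so they do not show whether total RNA differed.

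Most proximal tubule markers fell, 15 of 22 tested, while 2 rose. A lower share of proximal tubule cells alone would raise the markers of other cell types alike. The medians were 0.684 for the endothelial list, 0.515 for podocytes, 0.156 for the collecting duct and -0.403 for the loop of Henle and distal tubule. These lists did not move alike in these samples. The endothelial and the loop of Henle and distal tubule medians differed by 1.088 (permutation p = 0.00026). That pair was picked with its medians known and the test shuffles genes. The p therefore does not decide whether a lower share of proximal tubule cells was the sole cause. Reduced expression of male-biased kidney genes remains a candidate explanation for part of the fall. In male mice these genes depend on androgen. A set of 11 male-biased genes was drawn up, but not all of them were new to the analysis. Of these 9 fell and 2 rose, whereas of 17 other proximal tubule markers 10 fell and 2 rose. The median of the male-biased set was -1.094 against -0.516, a difference of -0.578, which is the size the explanation predicted, but with a permutation p of 0.064 the 2 sets cannot be told apart here. Cyp2e1, Slc22a6 and Cyp4b1 of this set were also members of the lists fixed before, and the fall of Cyp4b1 is reported above. The difference therefore does not come from unseen genes alone. Cyp4a12b went the other way, from 13.5 to 61.0 FPKM on average. Injury of the cells by crystals or by glyoxylic acid itself stays open as well and was not tested, since the design gives no stone group without crystals.

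As deposited, most ribosomal protein genes were higher and most oxidative phosphorylation genes lower. Of 79 tested ribosomal protein genes 68 rose and 1 fell (25 and 3 after median-of-ratios scaling), with a median of 0.461, while the oxidative phosphorylation list had a median of -0.407. After the fold change was fitted on transcript length and GC content over all other genes, which accounted for 1.9% of the variance, the median residuals were 0.356 and -0.563, a difference of 0.919 (permutation p = 1e-05, the smallest the resampling can give). This p treats genes that move together as independent and does not measure the spread between samples. With an estimated correlation the ribosomal list had an unadjusted p of 0.397 (limma camera). Over the scalings tried, the lowest median of the ribosomal protein genes was 0.205 and the highest of the oxidative phosphorylation genes -0.128. The size of the residual difference, rather than that p, argues against length and GC content, as fitted here, as the whole cause in these samples. Neither median turned its sign under the scalings tried. Equal FPKM sums, median-of-ratios scaling and totals without Kap moved the typical gene by 0.242, -0.224 and -0.044. These shifts are smaller than either list median, so they could hardly have turned a sign, and the kept signs decide nothing. Scaling by 1 factor per sample cannot change the distance between the lists, so it was not a test of that distance. Quantile normalization, which can, left medians of 0.516 and -0.307. Reads shared with ribosomal protein pseudogenes and differences in library handling between groups were not tested, so a biological cause may be put forward only as a hypothesis.

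The 6 samples can be split into 3 against 3 in 10 ways, which is too few for a share under 0.05. The real split gave 7067 genes and the highest of the other splits 0 (limma, with 27 to 285 genes at an unadjusted p below 0.05 in the other splits and 7750 in the real one), so 1 of the 10 splits gave as many genes. For gene lists by camera with the preset correlation the real split gave 23 and the highest other 21, and again 1 of the 10 splits gave as many. The preset correlation called 6 to 21 lists in splits that mix stone and control samples unevenly. In these splits the difference between stone and control remains in part and also widens the spread within groups. Neither the 0 genes nor the 6 to 21 lists are therefore rates of false calls.

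Fat cell genes were present in control sample 2 and stone sample 3. Cfd was at 81.8 FPKM in control sample 2 and 160 FPKM in stone sample 3 and listed at 0 in the other 4 samples, and Ucp1 was at 37.03 FPKM in control sample 2 and at 0.86 FPKM or less in the others. Without control sample 2 there were 4585 higher and 1497 lower genes, and without stone sample 3 there were 4411 and 1436. Among immediate early genes, Egr1 measured 3.02, 42.9 and 136 FPKM in control samples 1 to 3 and 28.0, 39.8 and 41.3 FPKM in stone samples 1 to 3.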
